A study of Homo sapiens and Drosophila melanogaster with 12 samples.

How the data were processed

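Small RNA was sequenced from 12 clonal cell lines in 4 groups of 3, wild type or knockout for ZSWIM8 in human K562 cells and for its fly counterpart (zswim8, also named Dora) in Drosophila S2 cells. Per the labels' protocols, RNA was harvested with TRI-Reagent and small-RNA libraries were made from total RNA. Cutadapt, with no version, and DESeq2 1.18.1 are named in the submitters' processing notes. The aligner or counter, the miRNA annotation, the genome builds and the read filters are not given in the sources used here.

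The deposited K562 table held a raw read count per miRNA and clone, with 2517 rows, of which 1250 had a count above 0 in at least 1 clone. The table also held a normalized signal per clone, which the authors made by dividing the counts by 1 size factor per clone. The authors' K562 log2 fold changes, knockout over wild type per the file headers, were smaller in size than those refitted with DESeq2 without a prior, 1.38 in the authors' deposited table against 1.63 for miR-7-5p. In 303 rows the deposited statistic, a score, differed by over 0.01 from the fold change divided by its SE. The deposited adjusted p-value of the K562 table was a Benjamini-Hochberg value over the 1249 rows with a p, recomputed here to within 8.17e-07. A further 6 columns of transformed values per sample were not used here.

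The S2 table held the authors' comparison alone, for 96 miRNA arms, with a mean normalized count, a log2 fold change and its SE. Values per S2 clone were not analysed here. Per the file headers, 2 more S2 columns were a p-value and an adjusted p-value, but their deposited values were of another kind. The first was the Wald score, equal to fold change divided by SE to within 2.78e-08 in every row. The second was the unadjusted two-sided p-value of that score, to within 0.314% in every row. The plan made before the data were examined was to take the adjusted p as the table gave it. Because that column was unadjusted, Benjamini-Hochberg values over the 96 arms were computed from it and used throughout for S2.

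K562 counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM factors, filterByExpr with its defaults), knockout against wild type with no covariate, in R 4.3.3. The filter kept 402 miRNAs, which held at least 99.87% of the counts of each clone. Values per clone are CPM, counts scaled by edgeR to a common library size with TMM factors. The SE of an edgeR log2 fold change was taken as its size divided by the square root of the F statistic. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 in both cell types. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 served for the S2 table, and figures were drawn with matplotlib 3.10.9.

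K562 totals ranged from 898695 to 1817816 counts, and 3 counts in a library, taken as the floor, corresponded to between 1.62 and 3.36 CPM. Depth was unknown for the S2 clones, whose deposited mean normalized count per arm ranged from 17.4 to 834353, so arms below that range were not analysed here. The libraries came from separate clones, so the p-values for K562 measure the spread between clones.

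For hairpins with both arms in the S2 table and a called rise in at least 1 arm, the difference of the log2 fold changes was tested with a normal approximation whose SE combined those of the arms. That SE treats the arms as independent. In K562 the log2 ratio of the arms was computed per clone after adding 0.5 to each count, with an exact two-sided permutation test, for which 0.1 is the smallest p that 3 against 3 clones allow. The change of miR-7-5p was compared between cell types with the same normal approximation. Lists of miRNAs were fixed before the data were examined. In K562 they were tested with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry, on log2 CPM with a prior count of 2. In S2 the median of a list was placed among 10000 random lists of the same size, matched on 4 bins of mean, as a description. Lists with fewer than 3 measured members were given as values.

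The miRNAs named were set by a rule fixed before the data were examined. Among called miRNAs with a mean of at least 10 normalized counts it took, per cell type, the 12 largest rises, the 8 largest falls and the 5 smallest adjusted p. It added the other arm of each hairpin, the 3 highest means and miR-7-5p, and members of fixed lists could be named with their list. Since edgeR called no K562 miRNA, miR-146b-5p, miR-135b-5p and miR-375 were named for their adjusted p in the authors' deposited table, after their values were seen.

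On counts simulated from the K562 means for 402 miRNAs, edgeR recovered 40% of 100 miRNAs changed 2-fold and 75% of 100 changed 4-fold. It made 1 false call among 202 unchanged miRNAs. The simulation drew each miRNA independently, without differences shared by the miRNAs of a clone, and changed nearly as many miRNAs as it left unchanged. The adjustment is harsher where few miRNAs change, so these shares need not hold for the real clones. On simulated values for the 96 S2 arms, 97.4% of 20 arms changed by a log2 of 2 were recovered and 4.21% of calls were false. Each S2 value was drawn with the deposited SE and tested with that same SE, so the false share follows from the adjustment. It cannot show whether the deposited SEs hold for the S2 clones. Alternatives covered the tool, the scaling, the filter on low counts, the adjustment, the threshold, a minimum fold change, re-centring, the clone number as a block and each K562 clone left out. The human positions given are those of GRCh38 in GENCODE release 29, and they were used for annotation only. No fly annotation was used here.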

Results

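The data were miRNA profiles of clonal lines of 2 cell types, each wild type or knockout for ZSWIM8, the substrate receptor of a Cullin-RING ubiquitin ligase. The study asked about target-directed miRNA degradation, in which pairing to a particular target RNA leads to decay of the miRNA. K562 is a human erythroleukaemia line; the sample titles name it K562i, a suffix whose meaning is not given in the sources used here, and the cell type label names it K562. S2 is a line from Drosophila embryos. Each of the 4 groups had 3 clones, grown from single sorted cells after transfection with Cas9 and a guide RNA against the gene or a non-targeting guide RNA. The wild-type K562 clones had 1494197, 1529918 and 1817816 miRNA counts, and the knockout clones had 1168876, 1253357 and 898695, so that each knockout library was shallower than each wild-type library. ZSWIM8 lies at chromosome 10, 73785582 to 73801797 (GRCh38, plus strand). Its mRNA is not measured by small-RNA sequencing, so the knockout itself was not checked here.

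The first comparison asked which miRNAs differed between knockout and wild-type S2 clones. The authors' deposited table gave miR-7-5p, a conserved miRNA with roles in photoreceptor and sensory organ development, the largest rise, a log2 fold change of 4.03 (SE 0.20), or 16.4-fold with a 95% interval of 12.4 to 21.5. In the authors' deposited table miR-12-5p rose nearly as much, by a log2 of 4.01 (SE 0.38), followed by miR-1012-3p with 3.34 (SE 0.57). The same direction was found for miR-996-3p (2.79, SE 0.27), miR-999-3p (2.73, SE 0.20) and miR-190-5p (2.73, SE 0.14) in the authors' deposited table. Falls were led in the authors' deposited table by miR-278-3p, with a log2 fold change of -2.48 (SE 0.51), and miR-252-5p, with -2.02 (SE 0.44).

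At a Benjamini-Hochberg adjusted p under 0.05, computed from the p-values of the authors' deposited table, 34 of 96 arms were called, 20 higher and 14 lower in knockout clones. Those p-values rest on a normal approximation that takes SEs from 3 clones per group as exact, so they may be too small. In K562 the Wald test of DESeq2 called 4 miRNAs where the F test of edgeR called 0. The S2 count is therefore not comparable with the edgeR count in K562. Further rises in the authors' deposited table were those of miR-9b-5p (log2 fold change 2.44, SE 0.15), miR-279-3p (2.02, SE 0.18), miR-9c-5p (1.92, SE 0.14) and miR-277-3p (1.70, SE 0.22). The last of the 12 largest rises were miR-1002-5p, at 1.27 (SE 0.22), and miR-304-3p, at 1.15 (SE 0.41), in the authors' deposited table. Smaller falls in the authors' deposited table were those of miR-1009-3p (-1.70, SE 0.37), miR-9388-5p (-1.34, SE 0.36), miR-1008-3p (-1.03, SE 0.38) and miR-967-5p (-0.96, SE 0.38). They were followed by miR-281-2-5p (-0.90, SE 0.23) and miR-1007-3p (-0.87, SE 0.23) in the authors' deposited table. The Benjamini-Hochberg adjusted p computed from the authors' deposited table was 1.81e-86 for miR-7-5p, 1.28e-85 for miR-190-5p, 5.12e-61 for miR-9b-5p, 2.93e-42 for miR-999-3p and 1.15e-39 for miR-9c-5p.

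The most abundant arms did not pass the test. In the authors' deposited table bantam-3p, a growth-promoting miRNA with a mean of 834353 normalized counts, had a log2 fold change of -0.11 (SE 0.24). There miR-14-3p stood at 0.00 (SE 0.15) and miR-184-3p at 0.66 (SE 0.29, Benjamini-Hochberg adjusted p 0.0587), both from the authors' deposited table. With Bonferroni adjustment of the p-values of the authors' deposited table, 21 arms were called. The 13 arms that lost their call in this way were miR-34-5p, both arms of miR-283, miR-305-5p, miR-263a-5p, miR-304-3p, miR-184-5p and miR-92b-3p among the rises, and miR-1006-3p, miR-1008-3p, miR-9388-3p, miR-967-5p and miR-988-5p among the falls of the authors' deposited table. The deposited S2 comparison could not be recomputed without single clones, and 1 knockout clone carried the number 8 in its label, read here as a lane, where the other 5 S2 clones carried 1.

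**Figure D1:**
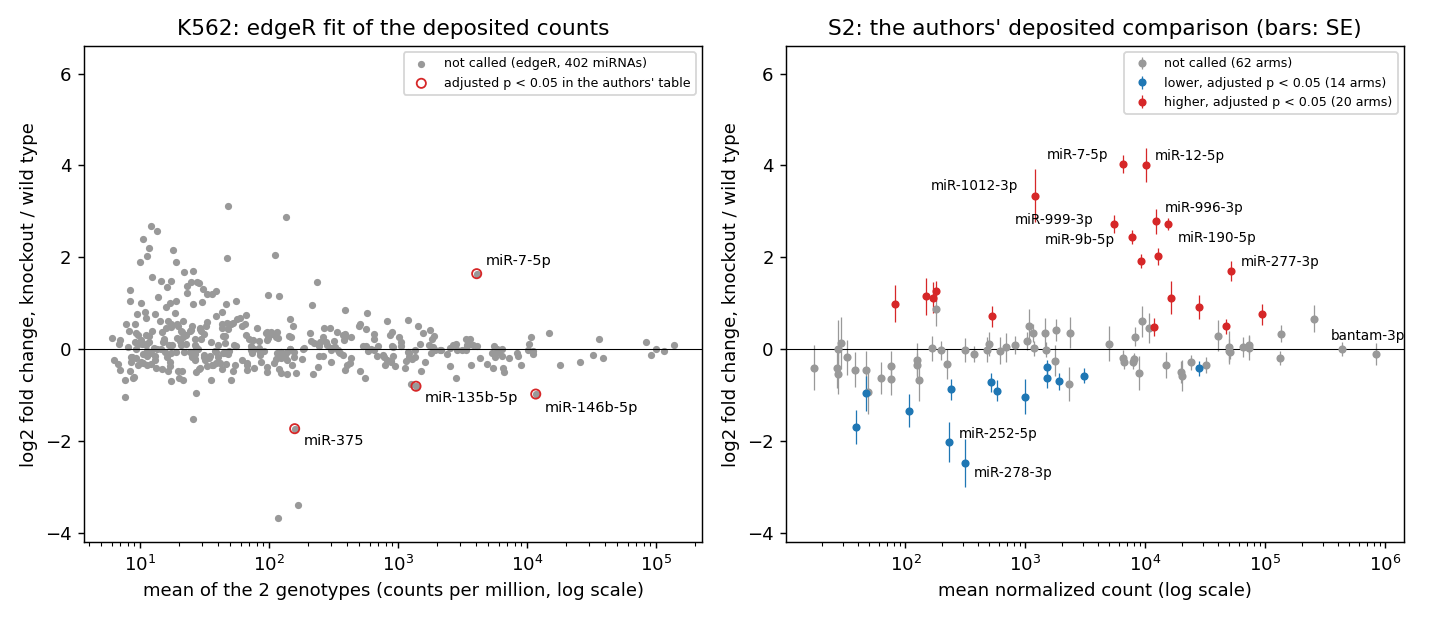
Log2 fold change, knockout over wild type, against mean level on a log scale, for the 402 K562 miRNAs fitted with edgeR (left, CPM) and the 96 S2 arms of the authors' deposited table (right, mean normalized count, bars are SE). Red and blue points on the right are the 20 arms called higher and the 14 called lower, and open red circles on the left are the 4 miRNAs past the threshold in the authors' deposited table.

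Fixed lists of fly miRNAs were described from the same comparison. Of 9 measured miRNAs reported elsewhere as sensitive to Dora, 8 rose in the authors' deposited table, among them miR-7-5p, miR-12-5p, miR-190-5p and miR-305-5p. Their median log2 fold change from the authors' deposited table was 2.44, at percentile 99.9 of random lists. Part of that list may rest on these same clones, so its count is not independent evidence. The ninth member, miR-304-5p, had a log2 fold change of 0.60 (SE 0.34) in the authors' deposited table. Adjusted over the list alone, the count from the authors' deposited table was also 8.

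Mirtrons are made from short introns by splicing in place of Drosha cleavage. Of 7 measured mirtron arms, 5 fell in the authors' deposited table, namely miR-1003-3p (-0.58, SE 0.16), miR-1006-3p (-0.62, SE 0.21), miR-1007-3p, miR-1008-3p and miR-1009-3p. A sixth, miR-1005-3p, had -0.92 (SE 0.48) in the authors' deposited table and was not called, and miR-1012-3p rose. The median of the list was -0.87 in the authors' deposited table, at percentile 0.755 of random lists matched on mean, and 6 of the 7 were called when adjusted over the list alone.

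Of 4 genomic clusters with a called listed arm, 2 also had uncalled listed arms. Of the 4 members of the miR-9c to miR-9b cluster, miR-9b-5p and miR-9c-5p rose, while miR-79-3p had -0.22 (SE 0.14) and miR-306-5p had -0.35 (SE 0.29) in the authors' deposited table. Counted as the fixed list of the miR-9 family, 2 of 3 measured members in the authors' deposited table rose. From the cluster of miR-12, miR-283 and miR-304, miR-12-5p and miR-283-5p (1.12, SE 0.36) rose in the authors' deposited table, which made 2 of 3 listed arms. The third listed arm, miR-304-5p, was not called in the authors' deposited table, while miR-304-3p rose. The calls of miR-283-5p and miR-304-3p from the authors' deposited table were lost with Bonferroni (adjusted p 0.172 and 0.468). Both members of the cluster of miR-277 and miR-34 rose in the authors' deposited table, with miR-34-5p at 0.76 (SE 0.23), as did both members of the cluster of miR-275 and miR-305, with miR-275-3p at 0.91 (SE 0.26) and miR-305-5p at 0.50 (SE 0.16). Adjusted over the list alone, each of these 5 lists had 2 calls from the authors' deposited table. Medians of the lists with at least 3 members lay at percentiles 82.9 (miR-9 family), 78.4 (miR-9c to miR-9b cluster) and 88.4 (cluster of miR-12) of random lists drawn from the authors' deposited table and matched on mean. Without matching the miR-9 family lay at percentile 97.95 in the authors' deposited table, outside the central 95%, and the clusters at 94.2 and 94.8.

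Of 7 measured members of the family of miR-2, miR-13, miR-11 and miR-308, whose seed pairs with K-box motifs, miR-308-3p fell (-0.70, SE 0.18) and 6 were not called in the authors' deposited table. The median of that family was 0.02, at percentile 61.7, and 1 was called adjusted over the list alone in the authors' deposited table. From the list of markers of other fly cell types, miR-263a-5p rose (0.71, SE 0.23) and miR-318-3p had -0.67 (SE 0.45) in the authors' deposited table, with 1 call adjusted over the list alone. From the miR-309 cluster, miR-6-3p had -0.45 (SE 0.41) in the authors' deposited table and was not called. Members of the miR-310 cluster and the let-7 complex were not analysed here.

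The second comparison asked whether the arms of a hairpin changed together, since both come from the same precursor. The difference between the arms was largest for miR-7, whose 5p arm rose while miR-7-3p had a log2 fold change of 0.02 (SE 0.27) in the authors' deposited table. In further hairpins whose higher-mean arm rose the other arm was also uncalled in the authors' deposited table. Among them were miR-190-3p at -0.01 (SE 0.26), miR-999-5p at -0.44 (SE 0.38) and miR-9b-3p at -0.10 (SE 0.18). Others in the authors' deposited table were miR-996-5p at 0.09 (SE 0.19), miR-279-5p at -0.02 (SE 0.20), miR-9c-3p at 0.04 (SE 0.31) and miR-277-5p at 0.50 (SE 0.37). The other arms of miR-34-5p, miR-275-3p and miR-305-5p, which rose less, were uncalled too. In the authors' deposited table they had -0.19 (SE 0.16), 0.11 (SE 0.26) and 0.35 (SE 0.33). The arm miR-12-3p had 0.88 (SE 0.38, Benjamini-Hochberg adjusted p 0.0528), computed from the authors' deposited table, and was called with a mean of at least 100 normalized counts (adjusted p 0.0488, Benjamini-Hochberg). The lower-mean arm was called higher in 3 hairpins of the authors' deposited table. Both arms rose for miR-283, while for miR-184 and miR-304 the lower-mean arm alone was called.

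Both arms were listed for 32 hairpins, of which 15 had a called rise in at least 1 arm in the authors' deposited table. The higher-mean arm had the larger log2 fold change in 13 of those 15 in the authors' deposited table, and in 11 of the 17 with no called rise. No test is given for these counts, since a hairpin enters the 15 through a called rise and the mean includes the knockout clones. The difference passed a Benjamini-Hochberg adjusted p under 0.05 in 11 hairpins of the authors' deposited table, with the higher-mean arm above in each. Those hairpins were selected by a called rise that the difference also uses, and the adjustment covered those 15 alone. A difference near the threshold is therefore less certain, such as that of miR-275 in the authors' deposited table (normal approximation, Benjamini-Hochberg adjusted p 0.0387). Differences in those 11 ran from 0.80 (miR-275) to 4.01 (miR-7) on the log2 scale in the authors' deposited table. The difference was not called for miR-184, miR-305, miR-283 and miR-304 in the authors' deposited table, and the arms of miR-283 both rose, by 1.12 (SE 0.36) and 1.12 (SE 0.34). A fall was called in 3 of the 32 hairpins of the authors' deposited table. Both arms of miR-9388 fell in the authors' deposited table, with -0.42 (SE 0.15) for the 3p arm. In the authors' deposited table miR-308-3p fell and miR-308-5p, at -0.25 (SE 0.34), was not called. For miR-988, named after its values were seen, the 5p arm fell (-0.38, SE 0.15) and the 3p arm, at -0.28 (SE 0.16), was not called in the authors' deposited table.

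**Figure D2:**
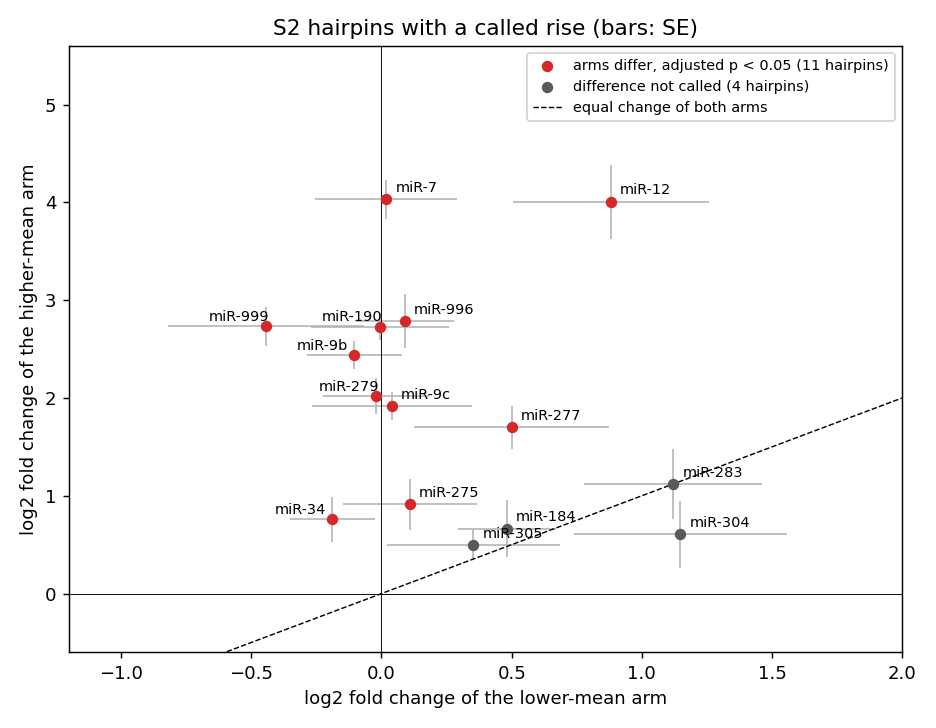
Log2 fold change of the higher-mean arm against that of the lower-mean arm for the 15 S2 hairpins with a called rise in the authors' deposited table, with SE bars on both axes and a dashed line for equal change. The 11 hairpins whose arms differed (red) lie above the line.

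The third comparison asked which miRNAs differed between knockout and wild-type K562 clones. The miRNA with the smallest p was again miR-7-5p, at 1967 ± 605 CPM in wild-type clones (SD, n = 3) and 6148 ± 923 CPM in knockout clones (SD, n = 3). Its log2 fold change was 1.64 (SE 0.25), or 3.13-fold, and each knockout clone lay above each wild-type clone, but the edgeR Benjamini-Hochberg adjusted p was 0.173. The other arm, miR-7-1-3p, was at 258.9 ± 49.96 CPM in wild-type and 287.6 ± 32.6 CPM in knockout clones (SD, n = 3), with a log2 fold change of 0.15 (SE 0.21). The log2 ratio of miR-7-5p to miR-7-1-3p was 2.90 ± 0.20 in wild-type and 4.41 ± 0.16 in knockout clones (SD, n = 3), a difference of 1.51 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 clones allow).

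Of the 402 miRNAs tested, edgeR called 0 at an adjusted p under 0.05 (Benjamini-Hochberg), and 19 had an unadjusted p under 0.05, 11 higher and 8 lower in knockout clones. DESeq2 called 4 without that filter, the same 4 on the 402 miRNAs the filter kept (an alternative chosen after seeing the data), and edgeR without the filter called 9. Those 4 miRNAs, miR-7-5p, miR-146b-5p, miR-135b-5p and miR-375, passed the threshold in the authors' deposited table. The log2 fold changes of the authors' deposited table were 1.38, -0.86, -0.74 and -1.19, with adjusted p (DESeq2) of 2.16e-06 for miR-7-5p and 0.0282 for each of the others.

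In the edgeR fit, miR-146b-5p, an arm known from inflammatory signalling, was at 15435 ± 3373 CPM in wild-type and 7852 ± 1745 CPM in knockout clones (SD, n = 3), a log2 fold change of -0.98 (SE 0.23). Values of miR-135b-5p were 1747 ± 207 and 1000.1 ± 193 CPM (SD, n = 3), a log2 fold change of -0.80 (SE 0.19). Those of miR-375, best known from pancreatic islets, were 242 ± 61.3 and 73.1 ± 36.5 CPM (SD, n = 3), a log2 fold change of -1.73 (SE 0.46). All 3 knockout clones lay below all 3 wild-type clones for each of these 3 miRNAs. Over all tested miRNAs, 11.4% had clones separated in this way in either direction, against 10% by chance.

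Mature miR-7-5p is made from 3 human loci and cannot be assigned to one of them. MIR7-1 lies on chromosome 9, 83969748 to 83969857 (minus strand), within HNRNPK. It overlaps an exon of at least 1 annotated transcript of that gene. MIR7-2 lies on chromosome 15, 88611825 to 88611934 (plus strand, in no other gene). MIR7-3 lies on chromosome 19, 4770670 to 4770779 (plus strand, in an intron of MIR7-3HG). The arm of the MIR7-2 hairpin, miR-7-2-3p, had 0 or 1 count in each clone. MIR146B lies on chromosome 10, 102436512 to 102436584 (plus strand), MIR135B on chromosome 1, 205448302 to 205448398 (minus strand, in an intron of LEMD1), and MIR375 on chromosome 2, 219001645 to 219001708 (minus strand).

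**Figure D3:**
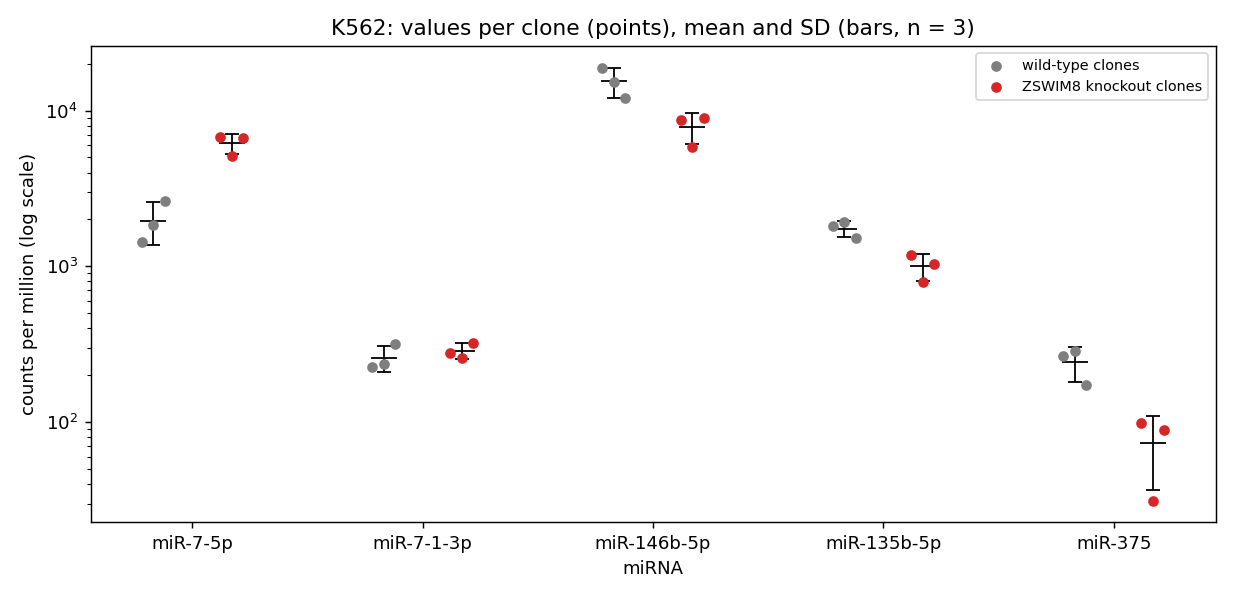
CPM (log scale) of 5 miRNAs in each K562 clone, with mean and SD bars (n = 3). For miR-7-5p the knockout clones lie above the wild-type clones, for miR-7-1-3p the groups overlap, and for miR-146b-5p, miR-135b-5p and miR-375 the knockout clones lie below.

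Fixed lists of human miRNAs had 0 called members in K562. Of 8 lists with at least 3 tested members, camera with the preset correlation called 3. The C19MC cluster, a primate-specific array expressed mainly in placenta, was higher in knockout clones, with positive log2 fold changes for 20 of 20 tested members (median 1.48, camera adjusted p 0.00158, Benjamini-Hochberg), but p = 0.397 with an estimated correlation (camera, not a permutation test). The list was fixed as a range of names, and 8 of its 48 rows, of the miR-513 and miR-514 families, lie on chromosome X instead, with 0 of them tested. Summed over the 40 rows on chromosome 19, the values were 36.0, 76.3 and 513.8 CPM in wild-type clones 1 to 3 and 55.5, 1394 and 562.1 CPM in knockout clones 1 to 3. The cluster of miR-424, miR-503, miR-450a and miR-542 was higher, with 7 of 7 tested members positive (median 0.40, camera adjusted p 0.0131, Benjamini-Hochberg), such as miR-503-5p at 0.66 and miR-424-5p at 0.61, but p = 0.308 with an estimated correlation. The let-7/miR-98 family was lower, with 8 of 9 negative (median -0.50, camera adjusted p 0.00238, Benjamini-Hochberg), such as let-7a-5p at -0.63 and let-7g-5p at -0.63, while let-7c-5p was at 1.31, but p = 0.246 with an estimated correlation. The camera calls hung on single clones. All 7 tested members of the cluster of miR-424 were lowest in wild-type clone 1, with miR-424-5p at 380.5, 639 and 930.2 CPM in wild-type and 723, 1336 and 913 CPM in knockout clones 1 to 3, and miR-450a-5p at 42.4, 87.1 and 137 against 110.1, 109 and 129.9 CPM, though the clones were fully separated for miR-503-5p and miR-424-3p. Without wild-type clone 1 the cluster was not called (camera adjusted p 0.379, Benjamini-Hochberg), nor without knockout clone 2 (0.117) or 3 (0.0588). All 9 let-7/miR-98 members were lowest in knockout clone 2, with let-7g-5p at 535, 808 and 655 CPM in wild-type and 530.8, 189 and 572 CPM in knockout clones 1 to 3, though the clones were fully separated for let-7a-5p. Without knockout clone 2 the let-7/miR-98 family was not called (camera adjusted p 0.286, Benjamini-Hochberg), nor was C19MC (0.508), which was also lost without wild-type clone 1 (0.153). Neither camera with an estimated correlation nor fry called any of the 8 lists at an adjusted p under 0.05.

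The other lists were not called by camera with all clones. Erythroid miRNAs were called lower without wild-type clone 1 (camera adjusted p 0.0410, Benjamini-Hochberg) and without knockout clone 1 (0.0283). Of 12 tested miRNAs reported as substrates of target-directed degradation in other cells, 8 were positive (median 0.09, mean -0.30), and 1, miR-7-5p, was called when adjusted over the list alone. It was also the call among the 2 tested miR-7 arms, adjusted over the list alone. Since miR-7-5p is the arm that the study follows, its place in these short lists may not be independent of these clones. In the list of reported substrates miR-221-3p and miR-222-3p had log2 fold changes of -3.38 and -3.68. Their summed counts were 906, 1423 and 10 in wild-type and 55, 91 and 15 in knockout clones. The miR-15/16 family was split, with 4 of 7 tested members positive (median 0.61) and the 3 most abundant negative, namely miR-16-5p (-0.34, SE 0.13), miR-15b-5p (-0.35, SE 0.16) and miR-15a-5p (-0.15, SE 0.10), each with all knockout clones below all wild-type clones. The miR-17/92 clusters had a median of 0.05 and a mean of 0.61 (12 tested, 7 positive), and erythroid miRNAs a median of -0.20 and a mean of -0.23 (10 tested, 2 positive). Markers of other cell types had a median of 0.01 and a mean of -0.02 (12 rows tested), and that list held miR-142, miR-126 and miR-223, which K562 cells express. Adjusted over the list alone, each list other than those with miR-7-5p had 0 calls.

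The fourth comparison set the change of miR-7-5p in S2 against that in K562. The log2 fold change was 4.03 in S2 in the authors' deposited table and 1.64 in the edgeR fit of K562. The difference, with S2 from the authors' deposited table, was 2.39 (SE 0.32, 95% interval 1.75 to 3.02, z = 7.40). The S2 value came from the authors' DESeq2 fit and the K562 value from edgeR, so the interval rests on 2 kinds of SE. The normal approximation also takes the edgeR SE, estimated with 6.54 degrees of freedom, as exact, so the interval is too narrow. The miR-7-3p arm in S2 and miR-7-1-3p in K562 were both uncalled, at 0.02 (SE 0.27) in the authors' deposited table and 0.15 (SE 0.21) in the edgeR fit.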

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

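All tests of explanations below, and the tests of conserved miRNAs other than miR-7-5p, were chosen after the results were seen. Groups of 3 clones were too small to look for single outlying samples. Of 8 pairs of miRNAs with the same name in both species, 2 differed in their change between S2 and K562. The change of miR-7-5p was larger in S2 by 2.39 on the log2 scale (Benjamini-Hochberg adjusted p 1.11e-12 over 8 pairs, normal approximation, S2 values from the authors' deposited table). That of miR-190-5p in S2 exceeded that of miR-190a-5p in K562 by 2.62 (Benjamini-Hochberg adjusted p 0.000132, with the authors' deposited table for S2). In K562, miR-190a-5p was at only 9.32 CPM in wild-type and 9.83 CPM in knockout clones. Both adjusted p-values take SEs from groups of 3 clones as exact, so they are too small.

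In S2, the higher-mean arm had a larger log2 fold change than the other arm in 13 of the 15 hairpins with a called rise in the authors' deposited table. An equal rise of both arms is argued against in 11 of 15 hairpins of the authors' deposited table, whose arms differed after adjustment. That argument is weakest near the threshold, as for miR-275, since a called rise selected these hairpins. An equal rise stays open in the other 4, whose 95% intervals of the difference hold 0. Too few reads in the other arm cannot account for 10 of the 15 hairpins. There the 95% upper limit of the other arm lay below the 95% lower limit of the higher-mean arm, from the authors' deposited table. At means under 473, 7 called arms of the authors' deposited table changed by at least 2-fold. They were picked for their size, so they cannot show whether other low arms were pulled towards 0, and shrinkage stays open. No biological explanation was tested.

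Of 7 mirtron arms in S2, 5 fell, miR-1005-3p was not called and miR-1012-3p rose in the authors' deposited table. A scaling factor that moves every arm alike does not account for it, since the list median lay at percentile 0.08 of unmatched random lists from the authors' deposited table, a rank that no scaling factor moves. Low expression does not either, at percentile 0.755 of lists matched on mean. The library whose label carries another number, read here as a lane, or a single clone, cannot be told apart from genotype, because 0 S2 columns hold values of a single clone. No biological explanation was tested, and a difference between clones in splicing or host gene expression stays open.

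Some K562 clones differed along an axis other than genotype. The first principal component (57.7% of variance) set wild-type clones 1 and 2 and knockout clone 1 (-12.5, -7.40, -7.94) apart from wild-type clone 3 and knockout clones 2 and 3 (5.72, 14.7, 7.39). Library depth is argued against, because the deepest and the shallowest library lay 6.17% of its range apart. Against a swap of wild-type clone 3 and knockout clone 1, their miR-7-5p to miR-7-1-3p log2 ratios of 3.05 and 4.59 lay with the other wild-type clones (2.67 and 2.97) and knockout clones (4.29 and 4.35). The swap stays open because that ratio is itself the outcome compared between genotypes, and no other marker of genotype was measured. Clone-specific miRNA clusters are a candidate explanation, with an estimated correlation of 0.971 among C19MC members, but 1 library per clone cannot separate clone from library.

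The 10 splits of the 6 K562 clones are too few for a share under 0.05. With edgeR the real split called 0 miRNAs, so 10 of 10 splits gave as many, and the highest other split called 21. With DESeq2 the real split called 4, the highest other split called 41, and 2 of the 10 splits gave as many. That other split is the one along the first principal component. The component came from the same values, so the count of this split restates that axis and is not separate evidence for it.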

How the results depend on the processing

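The K562 count of 0 moved with the tool and the filter: 4 with DESeq2, 9 without the filter on low counts, and, chosen after seeing the data, 4 with DESeq2 on the miRNAs kept by the edgeR filter, 4 with a DESeq2 fold change prior and 4 in the authors' deposited table. With the filter held the tool alone moved the count for DESeq2, while limma-voom called 0. For miR-7-5p the log2 fold change was 1.64 both in edgeR (SE 0.25) and in DESeq2 (SE 0.26). Its unadjusted p was 0.00043 in edgeR, from an F test with 6.54 denominator degrees of freedom, and 5.41e-10 in the DESeq2 Wald test. The SE was also alike for miR-146b-5p (0.23 and 0.25), miR-135b-5p (0.19 and 0.20) and miR-375 (0.46 and 0.46). A different effect or spread is thus argued against for these 4 miRNAs, and the tests differed in the p taken from them. The count was 0 under the other settings, among them 0 without any 1 clone and 0 with the clone number as a replicate block. The clone numbers do not pair the K562 clones: deviations of same-numbered clones correlated at 0.41, -0.22 and 0.48, and not every clone correlated best with its own number. No paired analysis was possible for S2 because values per clone were not analysed here, and leaving out S2 clones was not run for the same reason. Without wild-type clone 3 DESeq2 called 8, and without knockout clone 1 it called 13, each time with miR-7-5p, miR-146b-5p, miR-135b-5p and miR-375 among them. Without knockout clone 2 it called 2, miR-7-5p and miR-375. Without wild-type clone 1, wild-type clone 2 or knockout clone 3 it called 1, miR-7-5p. The DESeq2 calls of the 3 falls were thus each lost without any 1 of several clones, and that of miR-7-5p was never lost. Leaving out a clone also leaves fewer clones to test with. In edgeR the 3 falls kept their sign without any 1 clone. Their log2 fold changes ran from -0.77 to -1.15 (miR-146b-5p), -0.66 to -0.97 (miR-135b-5p) and -1.36 to -2.05 (miR-375). The lost calls thus do not show that a single clone carried the falls.

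Over 20 alternatives the K562 log2 fold change of miR-7-5p lay between 1.38 and 1.88, with adjusted p from 2.17e-07 to 0.952 (edgeR, DESeq2, limma or the authors' deposited table), and 5 passed the threshold. The S2 minus K562 difference ranged from 2.15 to 2.54 without 1 K562 clone and kept its side throughout. The S2 count of 34 from the authors' deposited table fell to 21 with Bonferroni, which is stricter, and to 19 with a minimum log2 fold change of 1, added after seeing the data; the column headed as adjusted gives 38 at face value. Re-centring by 0.02 turned the uncalled values of miR-7-3p (-0.0012) and miR-14-3p (-0.0194) of the authors' deposited table below 0. The 11 hairpins were 10 to 11 in each alternative. Camera calls in K562 moved from 3 to 0 with an estimated correlation and to 0 with fry; without 1 clone, chosen after seeing the data, they ranged from 0 (knockout clone 2) to 4. S2 lists outside the central 95% went from 2 to 3 without matching, with the miR-9 family added. K562 depth limits what can be seen: 3 counts are up to 3.36 CPM.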

Other observations

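Several K562 miRNAs differed widely between clones of 1 genotype. These were picked after their values were seen, and no explanation was tested for them. Summed miR-221-3p and miR-222-3p, a pair from 1 cluster, stood at 652, 905 and 5.39 CPM in wild-type clones 1 to 3 and at 45.5, 73.3 and 16.8 CPM in knockout clones 1 to 3. For miR-20b-5p and miR-363-3p, from the miR-106a cluster, summed counts were 1, 1 and 35 in wild-type and 1, 70 and 69 in knockout clones. The neural miRNA miR-9-5p had 69 counts in wild-type clone 1 and 3370 and 5397 in wild-type clones 2 and 3, against 2479, 1280 and 2841 in knockout clones. Across libraries, the highest correlation of log2 CPM over miRNAs, 0.98, was between wild-type clone 3 and knockout clone 3, and miRNAs are not independent replicates.

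Other miRNAs with the same name in both species gave values side by side. Human miR-33a-5p had a log2 fold change of -0.01 (SE 0.20) in the edgeR fit, human miR-33b-5p had 0.38 (SE 0.16) with each knockout clone above each wild-type clone, and fly miR-33-5p had -0.03 (SE 0.24) in the authors' deposited table. For miR-34, human miR-34a-5p had 0.93 (SE 0.80) and fly miR-34-5p rose by 0.76 (SE 0.23) in the authors' deposited table. Human miR-92b-3p had 0.15 (SE 0.21), and fly miR-92b-3p rose by 0.99 (SE 0.40) in the authors' deposited table. For miR-9, human miR-9-5p had 0.30 (SE 1.14), while fly miR-9b-5p and miR-9c-5p rose by 2.44 and 1.92 in the authors' deposited table, and the differences were not called (Benjamini-Hochberg adjusted p 0.125 and 0.221 over 8 pairs). The log2 ratio of miR-146b-5p to miR-146b-3p was 8.81 ± 0.34 in wild-type and 8.70 ± 0.21 in knockout K562 clones (SD, n = 3; exact two-sided permutation p = 0.7). That of miR-135b-5p to miR-135b-3p was 5.54 ± 0.32 in wild-type and 6.56 ± 1.11 in knockout clones (SD, n = 3; exact two-sided permutation p = 0.3), with miR-135b-3p at 69, 53 and 57 counts in wild-type and 29, 4 and 11 in knockout clones (log2 fold change -1.52, SE 0.65, not called).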
